A study of Homo sapiens with 6 samples.

How the data were processed

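RNA-seq was run on 6 libraries of cells whose titles name both EA.hy926 and human umbilical vein endothelial cells. EA.hy926 is an established hybrid line made by fusing such a cell with A549, a lung carcinoma line. The name EA.hy926 is used below, but the identity of the cells could not be settled from the labels. The labels describe 3 control libraries and 3 libraries from cells exposed to lipopolysaccharide (LPS, the outer membrane glycolipid of Gram-negative bacteria) at 1000 ng/ml for 12 h. Groups were taken from the sample titles, because the treatment field reads the same for controls and LPS samples. The labels do not show that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

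All 5 deposited tables hold FPKM (fragments scaled to transcript length in kilobases and to mapped fragments), as calculated by the authors. The tables cover protein-coding genes, protein-coding transcripts, transcripts classed by the authors as long noncoding RNA (lncRNA), all annotated genes and all annotated transcripts. HISAT2 and StringTie are named without versions in the submitters' processing notes. Those notes name a mouse build, mm9, whereas the deposited FPKM tables carry human Ensembl identifiers at GRCh38 coordinates, so GRCh38 coordinates are given throughout. Of 61556 genes, 95.1% were found in GENCODE 29, and 72.6% of those had the same start and end. The all-transcript table also holds 33622 assembled transcripts with no Ensembl identifier. Read counts, counting strand and quantification options are not given in the sources used here, so overlapping, antisense and duplicated genes are treated as uncertain. Where 1 symbol had 2 gene identifiers, the one with the higher mean FPKM was used, a choice made after values were seen. SOD2 is such a case.

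FPKM carries no read depth. Summed FPKM of all annotated genes ranged from 427920 to 483345 per library, with 26436 to 27944 genes above 0. The most frequent low value of FPKM times length among single-exon genes over 1500 bases was taken as a step. If that step stood for a single fragment in every library, relative depth would lie between 83.4% and 100% of the deepest library. Only 25.6% to 29.7% of those genes' values were whole multiples of that step within a tolerance of 0.02, so no whole reads were recovered. Absolute depth is therefore unknown and relative depth uncertain. The small RNAs RN7SL1 (10.4%), RN7SK (9.59%) and RPPH1 (7.13%) took the largest shares of summed FPKM. No 2 libraries held the same data, since at most 0.0213% of nonzero values were identical in any pair.

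Features with a mean of at least 0.5 FPKM over the 6 libraries were tested on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3. The model held the group alone, with eBayes and a mean-variance trend, and gave two-sided p-values adjusted by the Benjamini-Hochberg method within each table. An adjusted p under 0.05 was the threshold. Every adjusted p for a gene or transcript below comes from this test. Log2 changes are on the log2(FPKM + 0.5) scale, which understates changes of low features. Values are mean FPKM ± SD over n = 3 libraries per group.

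Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 of 30 lists with at least 5 tested members. Camera with a correlation estimated per list and fry were run beside it. Fry asks whether a list's genes move on balance in 1 direction, and its mixed form whether they change in either direction. Members were also adjusted over the list alone. The erythroid and leukocyte marker lists had too few tested members.

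Tests, gene lists, most alternatives and the rule for named features were fixed before the data were examined. From the protein-coding gene and lncRNA transcript tables, the rule takes up to 10 rises and 10 falls past the threshold with a mean of at least 1 FPKM and no overlap between groups. From each list it takes up to 4 members past the threshold with the largest changes, or the 3 most abundant where none passed, and it adds a fixed set of LPS response genes. A gene that the rule names among the rises is not reported here. Counting a list member as past the threshold by either adjustment was decided after values were seen. Results were recomputed with pseudocounts of 0.1 and 1, without a filter and with a minimum of 1 FPKM, after median-of-ratios rescaling and quantile normalization. Further alternatives were a block for replicate number, library weights (arrayWeights), robust eBayes, leaving out each library, and unadjusted p under 0.05 with a change of at least 2-fold. A pair of lncRNA alternatives was chosen after seeing the data, namely only transcripts of genes not annotated as protein-coding, and those transcripts summed per gene.

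The procedure was tested on simulated data with the real means, normal noise with spreads as moderated by eBayes, and 200 changed features per table. Among 12068 protein-coding genes, 83% of 2-fold and 99% of 4-fold changes were recovered, with 12 false calls among 194. Among 15944 annotated genes the shares were 62% and 97%. Among 20563 protein-coding transcripts they were 0% and 11%, and among 8297 lncRNA transcripts 0% and 0%. Under such noise, changes of up to 4-fold would mostly be missed in the transcript tables. These shares hold for 200 planted changes, and where fewer features change the adjustment is stricter and fewer would be recovered. The simulated noise holds no transcripts that switch on or off from library to library, so it cannot show how many false calls these give. False calls were 0 in both simulated transcript tables. Real libraries regrouped with control and LPS mixed gave 18 to 30 calls among protein-coding transcripts and 3 to 12 among lncRNA transcripts. In the real data, 6 of 105 protein-coding genes with an unadjusted limma p under 0.05 and at least 2-fold change were called. Analyses used Python 3.11.15, and figures were drawn with matplotlib 3.10.9.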

Results

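Transcript abundance was measured by RNA-seq in cells labelled EA.hy926, an endothelial hybrid line, in 3 control libraries and 3 libraries from cells given LPS at 1000 ng/ml for 12 h. The series asks which long noncoding RNAs, and by its design which genes at large, differ between LPS-treated and control endothelial cells. Summed FPKM of protein-coding genes ranged from 256047 to 264878 per library, and 11078 to 11179 protein-coding genes reached 1 FPKM. Pairwise correlations of log2 values across protein-coding genes, which are not independent replicates, were 0.971 to 0.976 within groups and 0.962 to 0.974 between groups. Across lncRNA transcripts they were 0.639 to 0.672 within and 0.637 to 0.675 between groups.

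By camera with the preset correlation, interferon-stimulated, cytokine and NF-kB genes were higher in the LPS libraries as groups, while epithelial and A549 markers were lower. None of these 4 group calls held with an estimated correlation (adjusted p = 0.221, 0.373, 0.221 and 0.221), and of their members MX1 and ISG15 alone passed the adjustment over all genes. The interferon-stimulated GTPase MX1 rose from 0.847 ± 0.257 to 13.6 ± 7.71 FPKM (log2 change 3.27, SE 0.35). The ubiquitin-like modifier ISG15 rose from 17.1 ± 1.87 to 54.3 ± 9.76 FPKM (log2 change 1.63, SE 0.15). IL4R, the interleukin 4 receptor alpha chain, rose from 5.11 ± 1.37 to 18.7 ± 1.73 FPKM (log2 change 1.80, SE 0.18). BRD2, a bromodomain chromatin reader, rose from 13.1 ± 1.84 to 33.5 ± 2.28 FPKM (log2 change 1.33, SE 0.13). Of the called genes, 2 fell, UBTD2 from 4.11 ± 1.11 to 0.279 ± 0.0605 FPKM (log2 change −2.54, SE 0.21). The actin-binding coronin CORO1C fell from 88.8 ± 7.40 to 47.6 ± 0.738 FPKM (log2 change −0.89, SE 0.09).

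These 6 genes and 1 more, 5 higher and 2 lower with LPS, were the 7 past the threshold among 12068 tested protein-coding genes, each at a limma adjusted p of 0.0344. At an unadjusted p under 0.05 there were 1254 genes against 603.4 given by chance, and 105 of them changed at least 2-fold, 52 higher and 53 lower. The 3 control and 3 LPS values did not overlap in 17.4% of genes, where chance gives 10%. The count depended on single libraries, since it was 4 without control 1, 0 without control 2, 0 without LPS 2 and 2 without LPS 3, and of the 7 genes 1, 0, 0 and 0 remained. Without control 3 and without LPS 1 it was 5 and 8, and 2 and 3 of the 7 genes remained. By limma, the counts of 0 came with 1048 genes (without control 2) and 1214 genes (without LPS 2) at an unadjusted p under 0.05. The count was also 0 when low genes were not filtered out, with 1563 genes at an unadjusted p under 0.05.

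On GRCh38 the 6 named genes lie at chromosome 21 positions 41420304 to 41459214 (MX1), chromosome 1 positions 1001138 to 1014540 (ISG15), chromosome 16 positions 27313668 to 27364778 (IL4R) and chromosome 6 positions 32968594 to 32981505 (BRD2). UBTD2 spans chromosome 5 positions 172208414 to 172284090 and CORO1C chromosome 12 positions 108645109 to 108731596. MX1, ISG15, IL4R and BRD2 overlap antisense genes, BRD2 also overlaps HLA-DMA, and CORO1C and UBTD2 contain small RNA genes, so their levels are uncertain to that extent. The rise of BRD2 lay in the single transcript BRD2-219, which went from 0.233 ± 0.124 to 24.4 ± 2.54 FPKM. IL4R-202 went from 2.34 ± 0.652 to 15.0 ± 1.79 FPKM and MX1-202 from 0.228 ± 0.329 to 11.4 ± 7.01 FPKM. UBTD2-201 was listed at 4.25 FPKM in control 1, 4.95 in control 2 and 0 in the other 4 libraries, and in control 3 an assembled transcript of the gene stood at 2.89 FPKM.

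Of 34 tested interferon-stimulated genes, 33 had a positive log2 change, with a median of 0.61. Adjusted over the list alone, 17 rose and 0 fell, against 2 (MX1 and ISG15) adjusted over all genes. IFI6 rose from 23.5 ± 7.64 to 90.8 ± 48.5 FPKM (adjusted p over the list alone 0.00479) and OAS2, an oligoadenylate synthetase that senses double-stranded RNA, from 2.51 ± 0.206 to 9.28 ± 3.90 FPKM (0.00223). The camera adjusted p was 4.91e-20, and it ranged from 1.37e-21 to 9.81e-14, and the median from 0.49 to 0.74, when each library was left out. With an estimated correlation the adjusted p = 0.221. Relative to the control mean, the median over the list was 0.98 in LPS 1, 0.43 in LPS 2 and 0.56 in LPS 3 on the log2 scale, and LPS 1 also had the highest medians of the cytokine list (0.78) and the NF-kB list (0.55).

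Cytokine and chemokine genes were higher as a group (21 tested, median log2 change 0.45, camera adjusted p = 6.85e-05; adjusted p = 0.373 with an estimated correlation). Without LPS 1 the median was 0.30, with an adjusted p of 0.00047, and with a minimum of 1 FPKM it was 0.29. The adjusted p lay in a range from 1.19e-07 to 0.000657 over the alternatives with the preset correlation. Adjusted over the list alone, 6 rose and 1 fell, against 0 adjusted over all genes. CSF2, which encodes the granulocyte-macrophage growth factor, rose by that measure from 0.195 ± 0.0975 to 5.05 ± 3.17 FPKM (log2 change 2.86, SE 0.36). The chemokine CCL5 rose from 0.197 ± 0.194 to 3.12 ± 2.34 FPKM, the monocyte chemoattractant CCL2 from 5.49 ± 1.09 to 20.3 ± 12.8 FPKM and the pyrogenic cytokine IL1B from 4.64 ± 1.04 to 13.98 ± 6.65 FPKM. The neutrophil chemokine CXCL8 stood at 137 ± 12.3 and 171 ± 48.6 FPKM and IL6 at 8.22 ± 1.04 and 6.49 ± 0.901 FPKM in control and LPS libraries. Neither passed either adjustment.

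Adhesion molecules of activated endothelium had a median log2 change of 0.19 over 13 tested genes (camera adjusted p = 0.0244; adjusted p = 0.221 with an estimated correlation). On this list 3 genes rose and 0 fell adjusted over the list alone, against 0 over all genes. These were the leukocyte ligand ICAM1, from 40.0 ± 4.33 to 83.3 ± 23.7 FPKM, E-selectin (SELE), from 0.111 ± 0.0779 to 1.22 ± 0.735 FPKM, and the integrin ITGB3, from 50.1 ± 5.48 to 80.9 ± 12.9 FPKM. VCAM1 stood at 37.8 ± 4.49 and 24.7 ± 8.40 FPKM (log2 change −0.66, adjusted p over the list alone 0.102). The list's camera call was lost without control 3 (median 0.0761, adjusted p = 0.199), without LPS 2 (median 0.0148, adjusted p = 0.0858) and without LPS 3 (adjusted p = 0.0661), and the median was 0.29 without LPS 1. It was also lost without a filter (adjusted p = 0.149), with a minimum of 1 FPKM (0.11) and with library weights (0.0564), and over all alternatives with the preset correlation the adjusted p ranged from 0.00596 to 0.199.

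NF-kB pathway and feedback genes had a median log2 change of 0.38 over 23 tested genes (camera adjusted p = 4.69e-05; adjusted p = 0.221 with an estimated correlation). By adjustment over the list alone 6 rose and 0 fell, and 0 did so over all genes. ZC3H12A, an RNase that degrades inflammatory mRNAs, rose from 5.26 ± 0.252 to 8.75 ± 1.60 FPKM. The inhibitor NFKBIE rose from 6.11 ± 0.759 to 9.55 ± 1.31 FPKM. TNFAIP2 rose from 2.50 ± 0.313 to 3.93 ± 0.743 FPKM and the NF-kB inhibitor TNIP1 from 31.0 ± 5.03 to 44.9 ± 5.17 FPKM. NFKBIA stood at 47.8 ± 4.90 and 52.5 ± 7.07 FPKM, TNFAIP3 at 20.3 ± 2.76 and 27.4 ± 6.12 FPKM. SOD2, whose symbol has 2 gene identifiers, stood at 5.08 ± 1.022 and 8.04 ± 2.55 FPKM in control and LPS libraries. None of these 3 passed either adjustment.

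The LPS receptor and its signalling genes gave no call (24 tested, median log2 change −0.03, camera adjusted p = 0.834). TLR4, the LPS receptor, stood at 6.97 ± 1.1995 and 5.40 ± 1.37 FPKM in control and LPS libraries, its partner LY96 at 4.88 ± 0.431 and 4.73 ± 0.732 FPKM. The co-receptor CD14 stood at 0.729 ± 0.355 and 0.356 ± 0.0655 FPKM. The adaptor MYD88 was at 9.69 ± 1.08 and 10.1 ± 1.74 FPKM, IRAK1 at 38.6 ± 4.28 and 36.9 ± 2.50 FPKM, IRF3 at 15.0 ± 1.18 and 16.0 ± 1.80 FPKM. CASP4, a caspase that binds intracellular LPS, stood at 20.2 ± 2.03 and 16.6 ± 1.08 FPKM. Adjusted over the list alone, 0 of the 24 passed, as over all genes.

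**Figure D1:**
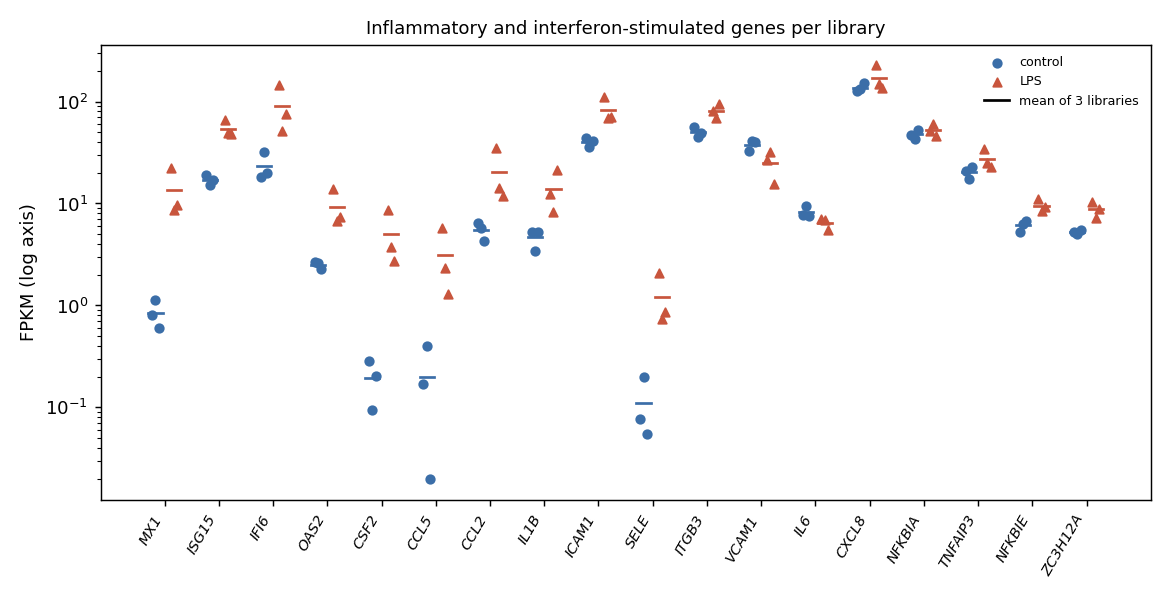
FPKM (log axis) of 18 named inflammatory and interferon-stimulated genes in each of the 3 control libraries (blue circles) and 3 LPS libraries (red triangles), with horizontal bars at the group means. MX1 and ISG15 passed the adjustment over all genes, and the LPS libraries lay above the controls without overlap for CSF2, CCL5, CCL2, IL1B, ICAM1 and SELE, but below them for VCAM1 and IL6.

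Vascular growth factor and Notch signalling genes were higher as a group (22 tested, median log2 change 0.27, camera adjusted p = 6.85e-05; adjusted p = 0.221 with an estimated correlation). With adjustment over the list alone 4 rose and 0 fell, against 0 over all genes. ESM1, an endothelial proteoglycan, rose from 39.4 ± 6.10 to 73.3 ± 12.2 FPKM. The growth factor PDGFB rose from 21.3 ± 3.53 to 36.5 ± 4.72 FPKM and PDGFA from 8.83 ± 0.919 to 15.1 ± 3.77 FPKM, and the Notch ligand JAG1 from 17.1 ± 1.61 to 27.6 ± 5.10 FPKM.

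Endothelial identity genes had a median log2 change of 0.17 over 31 tested genes (camera adjusted p = 0.0051; adjusted p = 0.575 with an estimated correlation). By adjustment over the list alone 3 rose and 2 fell, and 0 did so over all genes. The tight junction claudin CLDN5 rose from 17.9 ± 4.09 to 32.7 ± 3.63 FPKM and the vascular guidance receptor ROBO4 from 26.6 ± 3.64 to 38.0 ± 1.96 FPKM. In contrast, the sialomucin EMCN fell from 1.42 ± 0.285 to 0.394 ± 0.213 FPKM and MMRN1 from 29.1 ± 2.15 to 19.3 ± 4.26 FPKM. PECAM1 was at 55.6 ± 7.06 and 63.5 ± 1.16 FPKM, CDH5 at 82.0 ± 15.7 and 86.9 ± 17.3 FPKM and VWF at 129 ± 18.6 and 141 ± 30.0 FPKM in control and LPS libraries, with no call. The list's call was lost without control 3 (median 0.0971, adjusted p = 0.298) and without LPS 2 (median 0.0932, adjusted p = 0.311), in a range from 0.000114 to 0.311.

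Glycocalyx genes were higher as a group (16 tested, median log2 change 0.19, camera adjusted p = 0.00937; adjusted p = 0.221 with an estimated correlation), with 0 past the threshold adjusted over the list alone. The proteoglycan HSPG2 stood at 196 ± 5.35 and 243 ± 22.8 FPKM, GPC1 at 120 ± 2.41 and 139 ± 6.03 FPKM and SDC4 at 90.7 ± 6.995 and 83.4 ± 7.95 FPKM in control and LPS libraries. The call was lost without LPS 1 (adjusted p = 0.0553, in a range from 0.00248), and the median was 0.13 without control 3. Among coagulation and fibrinolysis genes (18 tested, median log2 change −0.09, camera adjusted p = 0.419), adjusted over the list alone 0 rose and 2 fell, against 0 over all genes. These were the protease inhibitor SERPINE2, from 23.4 ± 2.18 to 15.0 ± 0.994 FPKM, and the protein C cofactor PROS1, from 5.52 ± 0.673 to 3.69 ± 0.176 FPKM. Tissue factor (F3) stood at 16.1 ± 3.52 and 17.4 ± 2.37 FPKM and thrombomodulin (THBD) at 1.90 ± 0.409 and 1.99 ± 0.402 FPKM, with no call.

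Junction genes gave no group call (14 tested, median log2 change 0.14, camera adjusted p = 0.157), and CLDN5 was the 1 member that rose adjusted over the list alone, against 0 over all genes. Matrix and TGF-beta target genes also gave none (33 tested, median log2 change 0.08, camera adjusted p = 0.13), except without control 1 (adjusted p = 0.0281, in a range up to 0.558). Adjusted over the list alone, 4 of them rose, against 0 over all genes. The collagenase MMP1 rose from 186 ± 26.5 to 294 ± 47.2 FPKM and the stromelysin MMP10 from 0.958 ± 0.0335 to 2.72 ± 1.16 FPKM. The basement membrane collagen COL4A1 rose from 268 ± 28.8 to 377 ± 44.9 FPKM and COL4A2 from 249 ± 25.4 to 336 ± 28.7 FPKM.

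The sample titles name both EA.hy926 and umbilical vein endothelial cells, so what A549 markers stand for here depends on which cells these were. Epithelial and A549 lung carcinoma markers were lower as a group (10 tested of 28, median log2 change −0.44, camera adjusted p = 8.07e-05; adjusted p = 0.221 with an estimated correlation). Adjusted over the list alone, 6 fell and 0 rose, against 0 over all genes, and this was the 1 list that fry called in a single direction (adjusted p = 0.00889). Keratin KRT19 fell from 33.97 ± 1.23 to 23.1 ± 1.93 FPKM and KRT18 from 58.9 ± 5.88 to 41.4 ± 9.04 FPKM. The urea cycle enzyme CPS1 fell from 5.16 ± 1.35 to 3.37 ± 0.413 FPKM and the aldo-keto reductase AKR1C1, which has close paralogs and is uncertain, from 5.61 ± 1.21 to 3.68 ± 0.122 FPKM. Without a filter on low genes the median was −0.0558, with an adjusted p of 0.0227, in a range from 7.96e-05 over the alternatives.

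Fibroblast and smooth muscle markers were abundant in every library and gave no call (14 tested, median log2 change 0.00467, mean −0.08, camera direction down, adjusted p = 0.494), with 0 members past the threshold adjusted over the list alone. The fibrillar collagens COL1A1, COL1A2 and COL3A1 stood at 1395 ± 139, 1253 ± 71.9 and 811 ± 57.6 FPKM in controls and at 1526 ± 59.8, 1232 ± 83.9 and 666 ± 134 FPKM with LPS. Of 22 leukocyte markers 2 were tested. LAPTM5, a lysosomal membrane protein of blood cells, rose from 5.16 ± 1.21 to 8.53 ± 1.60 FPKM. By limma its adjusted p was 0.0201 adjusted over the list alone and 0.336 over all genes. PTPRC, the pan-leukocyte surface protein, was listed at 0 in all 6 libraries. No erythroid marker of the 10 reached the level for testing.

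**Figure D2:**
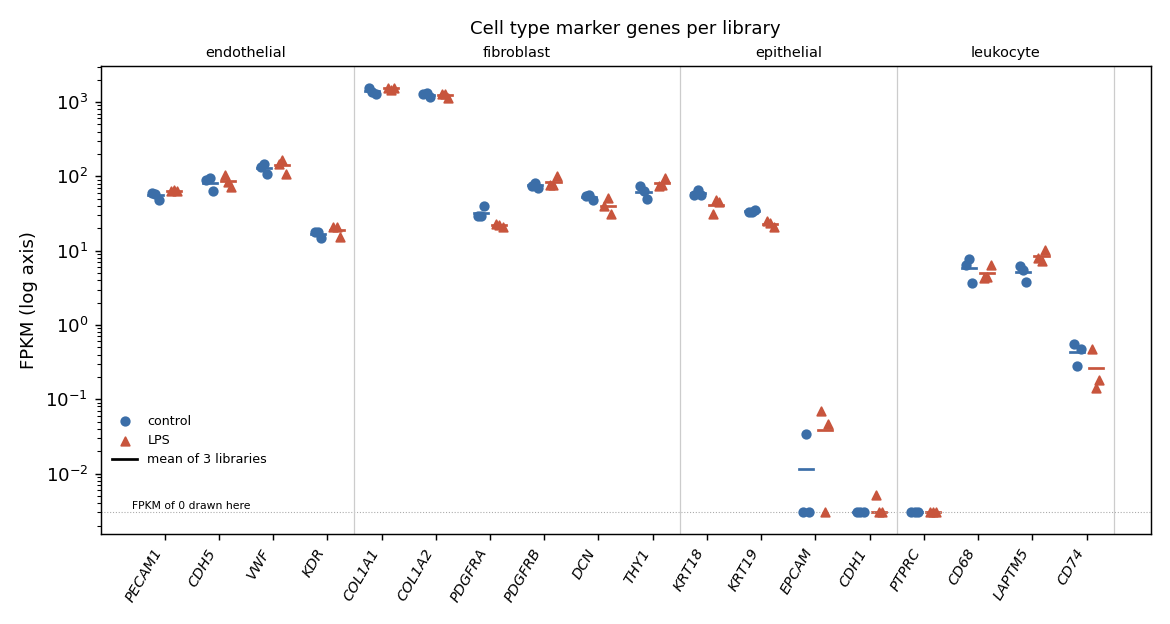
FPKM (log axis) of cell type markers from the fixed lists in each of the 3 control libraries (blue circles) and 3 LPS libraries (red triangles), with bars at the group means and values of 0 drawn at the dotted line. Endothelial and fibroblast genes were both abundant in all 6 libraries, KRT18 and KRT19 were lower with LPS, EPCAM and CDH1 were near or at 0, and PTPRC was listed at 0 throughout. Markers not given in the text were chosen for display after their values were seen.

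NRF2 antioxidant genes were lower as a group (23 tested, 20 negative, median log2 change −0.17, camera adjusted p = 0.000633; adjusted p = 0.221 with an estimated correlation). Its most abundant members stood at 2397 ± 48.0 and 2392 ± 85.0 FPKM (FTL), 495 ± 11.1 and 560 ± 66.9 FPKM (FTH1) and 248 ± 18.7 and 229 ± 11.9 FPKM (PRDX1) in control and LPS libraries. Ribosomal protein genes were also lower as a group (57 tested, median log2 change −0.08, camera adjusted p = 0.0199; adjusted p = 0.574 with an estimated correlation). RPL13A stood at 1360 ± 44.5 and 1341 ± 6.03 FPKM, RPS2 at 1354 ± 198 and 1323 ± 98.3 FPKM and RPL3 at 1326 ± 47.4 and 1235 ± 197 FPKM. The ribosomal call was lost without control 2 (median −0.0192, adjusted p = 0.531), without LPS 1 (adjusted p = 0.0514) and without LPS 3 (adjusted p = 0.172), in a range from 0.000124 to 0.531. In both lists 0 members passed adjusted over the list alone, and ferritin and ribosomal genes have many processed copies, so single levels are uncertain. The sign of FTL turned after median-of-ratios rescaling.

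Cell cycle genes were higher as a group (33 tested, 28 positive, median log2 change 0.18, camera adjusted p = 0.00122; adjusted p = 0.614 with an estimated correlation). PCNA, the replication clamp, stood at 26.9 ± 2.61 and 27.6 ± 2.94 FPKM, TPX2 at 10.5 ± 2.13 and 11.9 ± 2.30 FPKM and MCM6 at 10.4 ± 1.39 and 10.6 ± 0.407 FPKM in control and LPS libraries. The call was lost without control 2 (median 0.0503, adjusted p = 0.126) and without LPS 3 (median 0.0726, adjusted p = 0.0955), in a range from 1.02e-05 to 0.126, and the median was 0.27 both without control 3 and without LPS 2. Replication-dependent histones were higher too (16 tested, 15 positive, median log2 change 0.21, camera adjusted p = 0.000907; adjusted p = 0.469 with an estimated correlation), with a median of 0.13 without control 2. HIST1H1C was at 151 ± 5.81 and 170 ± 8.43 FPKM, HIST2H2AC at 137 ± 2.33 and 161 ± 17.4 FPKM and HIST1H3B at 71.2 ± 19.4 and 103 ± 14.8 FPKM, all uncertain as members of a family of near-identical genes. In both lists 0 members passed adjusted over the list alone.

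The remaining lists gave no call by camera with the preset correlation, and by limma 0 of their members passed adjusted over the list alone or over all genes. Cholesterol synthesis genes had a median log2 change of 0.10 (25 tested, camera adjusted p = 0.067). SREBF2 stood at 34.2 ± 0.663 and 35.7 ± 3.51 FPKM, FDPS at 37.0 ± 5.44 and 42.6 ± 10.2 FPKM and MSMO1 at 33.4 ± 5.01 and 35.5 ± 6.52 FPKM in control and LPS libraries. That list was called without control 1 (adjusted p = 0.0112), without LPS 1 (0.00725) and without LPS 2 (0.00703), and with a minimum of 1 FPKM (0.0425), in a range from 0.00703 to 0.738. Nuclear-encoded oxidative phosphorylation genes had a median of −0.07 (32 tested, camera adjusted p = 0.0599) and were called without control 3 (adjusted p = 0.00619), without a filter (0.0404), after quantile normalization (0.037) and with library weights (0.0366), in a range from 0.00619 to 0.278. In that list COX6A1 stood at 205 ± 3.64 and 207 ± 7.38 FPKM, ATP5F1B at 193 ± 22.9 and 169 ± 23.6 FPKM and COX8A at 152 ± 4.06 and 162 ± 14.5 FPKM. Mitochondrially encoded mRNAs had a median of −0.15 (9 tested, camera adjusted p = 0.211), and of −0.0173 without a filter. MT-CO1 stood at 924 ± 119 and 859 ± 83.2 FPKM, MT-CYB at 95.2 ± 6.98 and 85.3 ± 4.67 FPKM and MT-CO2 at 91.6 ± 9.03 and 79.9 ± 8.31 FPKM.

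Immediate early genes had a median log2 change of −0.05 (27 tested, camera adjusted p = 0.419) and were called only without LPS 2 (median −0.105, adjusted p = 0.000686, in a range up to 0.617). Their most abundant members were CCN2 at 591 ± 34.7 and 717 ± 12.0 FPKM, CCN1 at 346 ± 8.11 and 380 ± 7.70 FPKM and the phosphatase DUSP1 at 240 ± 11.3 and 198 ± 17.3 FPKM in control and LPS libraries. Unfolded protein response genes (25 tested, median −0.08, camera adjusted p = 0.617) included CALR at 412 ± 57.3 and 412 ± 31.2 FPKM, HSP90B1 at 255 ± 32.1 and 228 ± 32.8 FPKM and HSPA5 at 226 ± 13.7 and 225 ± 44.6 FPKM. Heat shock genes (15 tested, median −0.06, camera adjusted p = 0.368) included HSPB1 at 374 ± 25.9 and 367 ± 37.0 FPKM, HSPA8 at 310 ± 49.2 and 278 ± 27.6 FPKM and HSP90AB1 at 212 ± 10.9 and 215 ± 22.3 FPKM.

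Apoptosis and pyroptosis genes (22 tested, median log2 change 0.04, camera adjusted p = 0.419) included MCL1 at 97.8 ± 16.5 and 90.6 ± 1.80 FPKM, CFLAR at 50.6 ± 6.96 and 56.0 ± 4.09 FPKM and BCL2L1 at 28.2 ± 11.9 and 37.7 ± 12.9 FPKM in control and LPS libraries. For p53 targets the median was −0.00275 and the mean 0.02 (24 tested, camera direction down, adjusted p = 0.781). CDKN1A stood at 188 ± 142 and 208 ± 19.7 FPKM, GDF15 at 127 ± 30.1 and 113 ± 19.2 FPKM and TNFRSF10B at 82.9 ± 6.48 and 76.1 ± 2.65 FPKM. The control mean of CDKN1A rested on control 2, with 104, 352 and 109 FPKM in controls and 202, 230 and 192 FPKM with LPS. Hypoxia and glycolysis genes (28 tested, median −0.03, camera adjusted p = 0.519) included GAPDH at 2225 ± 198 and 2400 ± 147 FPKM, ALDOA at 549.4 ± 18.03 and 563 ± 50.9 FPKM and ENO1 at 499 ± 113 and 538 ± 134 FPKM. Housekeeping genes had a median of −0.01 (16 tested, camera adjusted p = 0.802). ACTB stood at 1494 ± 334 and 1542 ± 217 FPKM and RPLP0 at 676 ± 138 and 674 ± 143 FPKM. The signs of ACTB, GAPDH and CALR turned after quantile normalization, and that of RPLP0 after either scaling.

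In all, 13 of 28 lists were called by camera with the preset correlation, 9 higher and 4 lower with LPS. Some lists share members, such as KDR, FLT1 and ANGPT2 in the endothelial and vascular growth lists and CD44 in the adhesion and glycocalyx lists. The calls are thus not independent, and regrouping the libraries with control and LPS mixed gave 2 to 10 of them. With an estimated correlation 0 were called, where limma's camera gave 4 lists an unadjusted p under 0.05, and fry called 1 list in a single direction and 13 in its mixed form. Those 13 include 9 of the lists called by camera and 4 that camera did not call, namely coagulation (adjusted p = 0.00572), apoptosis (0.00603), junction (0.0284) and matrix genes (0.0284).

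**Figure D3:**
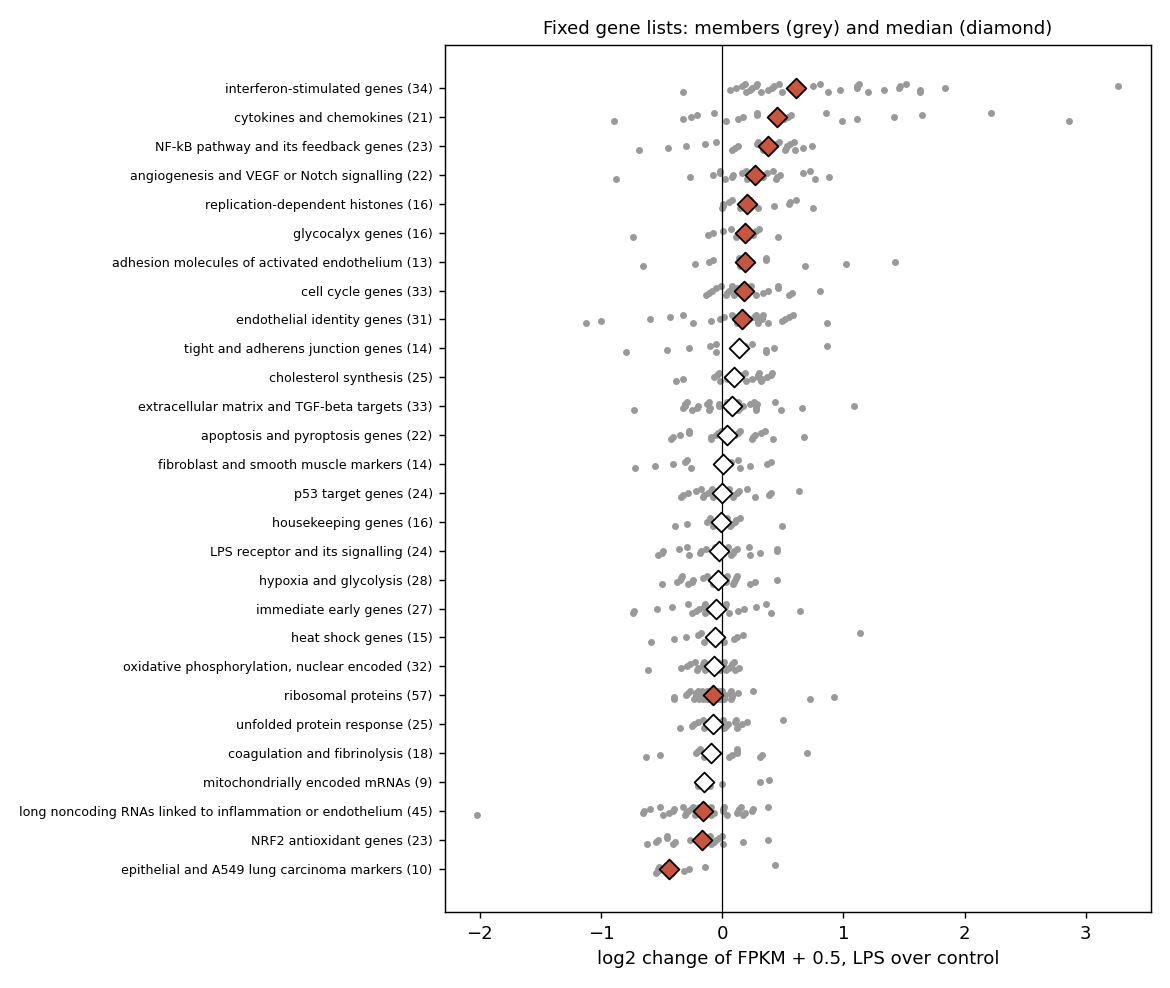
Log2 change (LPS over control, on log2(FPKM + 0.5)) of each tested member (grey points) of the 28 tested lists, with the number of tested members in parentheses and the list median as a diamond, red where camera's adjusted p with the preset correlation was under 0.05. The interferon-stimulated list has the highest median (0.61) and the epithelial list the lowest (−0.44), and 0 lists passed with an estimated correlation.

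Among transcripts classed as long noncoding, 3 rose and 4 fell with LPS. ATP5PB-201, from a gene for a subunit of the mitochondrial ATP synthase, fell from 47.8 ± 1.73 to 0.673 ± 0.583 FPKM (log2 change −5.53, SE 0.49). AC027319.1-201 stood at 7.23, 7.49 and 6.56 FPKM in controls and was listed at 0 in each LPS library. MSL1-207 fell from 6.13 ± 1.33 to 0.0321 ± 0.0192 FPKM and IGFBP7-202 from 4.92 ± 1.17 to 0.214 ± 0.0949 FPKM. ATP5F1C-204 rose from 0.451 ± 0.0878 to 6.63 ± 0.362 FPKM, AP003396.5-201 from 0.0328 ± 0.0568 to 8.34 ± 3.10 FPKM and AL118506.1-201 from 0.0641 ± 0.0293 to 2.16 ± 0.308 FPKM.

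These 7 were the calls among 8297 tested lncRNA transcripts, with limma adjusted p-values from 0.00737 to 0.0454, and at an unadjusted p under 0.05 there were 413 against 414.8 given by chance. Groups did not overlap in 10.8% of transcripts, where chance gives 10%. Regrouping the 6 libraries with control and LPS mixed gave 3 to 12 calls. Leaving out control 1, control 3, LPS 2 or LPS 3 left 0 calls each, with 373, 396, 410 and 427 transcripts at an unadjusted p under 0.05 by limma, leaving out control 2 left 1 that was not among the 7, and without LPS 1 there were 7, of which 2 were shared. Without a filter 1 call remained, AC027319.1-201.

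Of the tested lncRNA transcripts, 89.6% (7431) belong to genes that GENCODE 29 annotates as protein-coding, as do 4 of the 7 calls. The other 3 overlap further genes, AC027319.1 (chromosome 19 positions 4838332 to 4838907) antisense to PLIN3, AL118506.1 (chromosome 20 positions 63861212 to 63864293) antisense to ABHD16B, and AP003396.5 (chromosome 11 positions 119417951 to 119419114) opposite THY1 and within USP2-AS1, so their levels are uncertain. IGFBP7-202 (chromosome 4 positions 57030773 to 57065603) overlaps POLR2B on the other strand and is uncertain too. ATP5PB-201 spans chromosome 1 positions 111449465 to 111461332, ATP5F1C-204 chromosome 10 positions 7788184 to 7800052 and MSL1-207 chromosome 17 positions 40131991 to 40136118.

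Summed over all transcripts of the gene, IGFBP7 stood at 883 ± 139 and 844 ± 55.8 FPKM in control and LPS libraries, ATP5F1C at 53.3 ± 2.97 and 52.7 ± 2.28 FPKM, MSL1 at 16.7 ± 3.30 and 11.8 ± 0.558 FPKM and ATP5PB at 58.0 ± 0.242 and 40.6 ± 16.97 FPKM. In place of ATP5PB-201, the transcript ATP5PB-204 was listed at 35.2 FPKM in LPS 2 and 37.8 FPKM in LPS 3 and at 0 in the other 4 libraries. The totals of AC027319.1 were 12.9 ± 1.33 and 9.99 ± 1.70 FPKM, of AP003396.5 9.57 ± 1.85 and 12.95 ± 0.975 FPKM and of AL118506.1 1.78 ± 0.284 and 3.66 ± 0.580 FPKM.

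**Figure D4:**
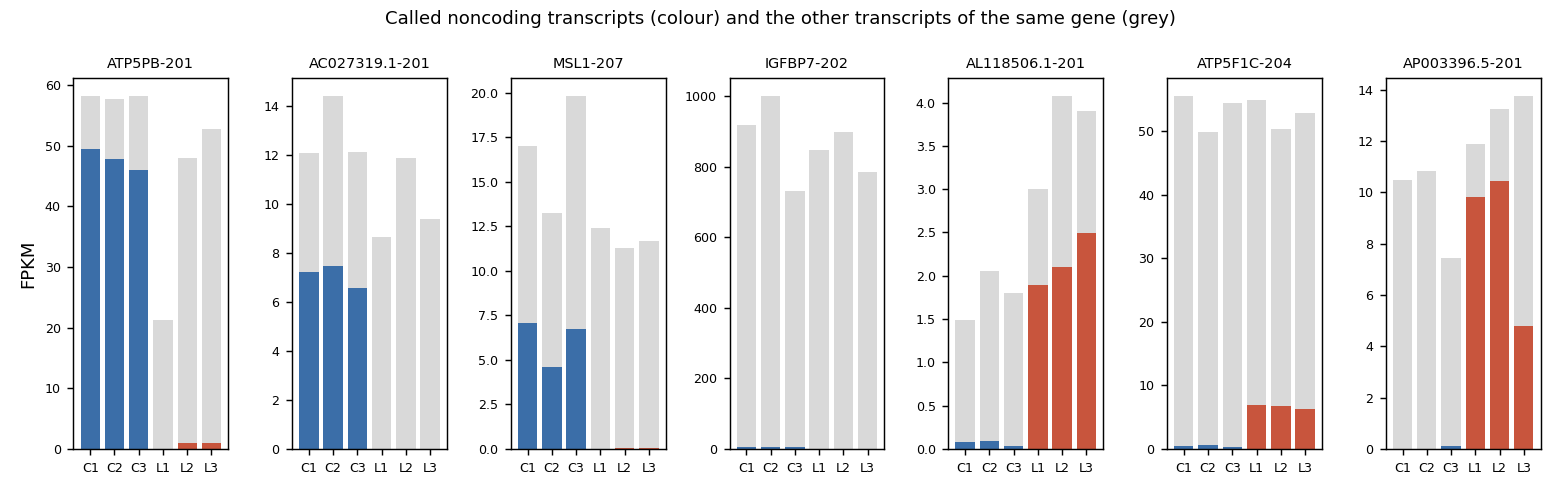
FPKM per library (C1 to C3 control, L1 to L3 LPS; each panel has its own axis from 0) of the 7 called lncRNA transcripts (blue in controls, red with LPS), stacked with the summed FPKM of all other transcripts of the same gene (grey). ATP5PB-201 made up most of its gene's FPKM in the controls, while IGFBP7-202 was 4.92 of a summed 883 FPKM.

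The fixed list of long noncoding RNAs linked to inflammation or endothelium was lower as a group in the table of all annotated genes (45 tested, 32 negative, median log2 change −0.16, camera adjusted p = 0.00937; adjusted p = 0.469 with an estimated correlation), with 0 members past the threshold adjusted over the list alone or over all genes. The call was lost without LPS 1 (median −0.0513, adjusted p = 0.224) and without a filter (0.149), in a range from 0.00308 to 0.224, and the median was −0.24 without LPS 3. NEAT1, the scaffold RNA of nuclear paraspeckles, stood at 18.9, 1.98 and 24.4 FPKM in controls and 0.413, 2.83 and 5.43 FPKM with LPS (log2 change −2.02, SE 0.98, adjusted p = 0.588). MALAT1 stood at 82.3 ± 38.9 and 91.2 ± 42.8 FPKM, RPPH1 at 32162 ± 6098 and 34699 ± 4803 FPKM and RMRP at 4632 ± 461 and 4419 ± 328 FPKM. VIM-AS1, which is antisense to its neighbour and uncertain, stood at 112 ± 15.8 and 97.9 ± 45.2 FPKM. In the lncRNA transcript table, 95 tested transcripts carried symbols of this list, and by limma 0 passed over the list alone or over all transcripts, with 6 at an unadjusted p under 0.05.

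At the level of single protein-coding transcripts, 11 were higher and 15 lower with LPS among 20563 tested, and 1324 had an unadjusted p under 0.05 against 1028 given by chance. Regrouping the 6 libraries with control and LPS mixed gave 18 to 30 calls, so these 26 calls are not set apart by their number. Without control 2, control 3, LPS 1 and LPS 3 the count was 49, 43, 43 and 41, of which 18, 17, 14 and 15 were among the 26. Over the lncRNA and protein-coding transcript tables together, 27 of the 33 called transcripts belonged to genes whose summed FPKM changed by less than 1.5-fold. Among all 15944 tested annotated genes, 6 were higher and 2 lower, and 1468 had an unadjusted p under 0.05 against 797.2 given by chance. That count was 3 without control 2, 4 without LPS 1, 1 without LPS 2 and 3 without LPS 3, of which 1, 2, 0 and 1 were among the 8. By limma it was 5 with a pseudocount of 1 and 5 after quantile normalization, and 0 without a filter, where 2196 genes had an unadjusted p under 0.05.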

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

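The comparison of isoform flips within and between groups was set before its ratio was computed, though single flips and the counts from other splits had been seen. The tests of changed isoform use, size factors, leukocyte genes and the fibroblast and endothelial lists, the counts over other splits and the highest flip ratio within reach of the called transcripts were chosen only after the result was seen.

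Transcripts that the authors' tables class as neither protein-coding nor long noncoding were outside the comparisons of the results, and 1 of them was higher and 2 were lower with LPS by limma among 6867 tested of 69995. An assembled transcript of RNA5-8SN4, a ribosomal RNA gene with many near copies and so uncertain, stood at 95.0, 114 and 48.8 FPKM in controls and at 0.0544, 0 and 0 FPKM with LPS (adjusted p = 0.0033). A transcript of SPOP, a ubiquitin ligase adaptor, stood at 5.56, 5.96 and 6.68 FPKM in controls and at 0.00425, 0 and 0 FPKM with LPS (adjusted p = 0.0033). The small nucleolar RNA SNORD16 stood at 0.0373, 0.0422 and 0.0541 FPKM in controls and at 2.26, 2.997 and 2.88 FPKM with LPS (adjusted p = 0.0239). At an unadjusted p under 0.05 there were 337 transcripts against 343.4 given by chance. With 10 splits of the 6 libraries the splits are too few for a share under 0.05; the real split gave 3 calls and the highest other 14, with 9 splits, the real one included, having as many or more.

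Most called transcripts changed while the summed FPKM of their gene changed little. Of 33 called over the lncRNA and protein-coding tables, 27 belonged to genes whose summed FPKM changed by less than 1.5-fold, and the median absolute log2 change was 3.62 for the transcripts against 0.25 for their genes. A flip was counted where a transcript with at least 5 FPKM in 1 library differed at least 8-fold from the other library while its gene differed by less than 1.5-fold. Pairs of libraries from different groups had 936.3 flips on average (880 to 966 over 9 pairs) and pairs within a group 933.5 (882 to 1007 over 6 pairs), a ratio of 1.003. The 33 called transcripts could raise that ratio to 1.035 at most, so it decides nothing about them, and with 33 calls from the real split and 37 from the highest other, isoform assignment that differs from library to library and isoform use changed by LPS cannot be told apart. BRD2-219 and IL4R-202 are among the 33. The gene FPKM is the sum over transcripts, so the same limit reaches the gene calls of BRD2 and of IL4R. It may reach the called falls too. In control 3 the FPKM of UBTD2 lay in an assembled transcript at 2.89, with UBTD2-201 at 0. CORO1C-202 stood at 11.7 FPKM in control 2 and at 0.0327 and 0 FPKM in controls 1 and 3.

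Interferon-stimulated genes were higher as a group by camera with the preset correlation, but not with an estimated one (adjusted p = 0.221), and 31, 22 and 28 of 34 lay above all controls in LPS 1, LPS 2 and LPS 3. A scaling difference between the groups is argued against by a ratio of mean size factors, LPS over control, of 0.9949, and by a median log2 change of 0.61 after median-of-ratios rescaling and 0.62 after quantile normalization. RNA from leukocytes is argued against by the summed FPKM of PTPRC, TYROBP, CD74, HLA-DRA, LYZ, CD3D, CD3E and NKG7, which reached at most 0.47 in an LPS library, where the summed rise of the 34 interferon-stimulated genes was 470 FPKM in LPS 1, 209 in LPS 2 and 163 in LPS 3. LAPTM5, also a leukocyte marker and not among these 8 genes, rose adjusted over the list alone from 5.16 ± 1.21 to 8.53 ± 1.60 FPKM, which is small beside that rise, and PTPRC was listed at 0 in every library. A response of the cells to LPS, or to interferon made in the culture, may remain as a hypothesis, but a culture or library batch that follows the groups was not tested, because the labels name none.

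Fibroblast genes lay beside endothelial genes in every library, with COL1A1 at 1395 ± 139 FPKM and VWF at 129 ± 18.6 FPKM in controls. If the source were a mixture of 2 cell types whose shares differed between libraries, the fibroblast and endothelial lists could be expected on opposite sides of their group means, which was so in 2 of 6 libraries. A mixture in equal shares in every library, or 1 cell population that expresses both sets, would leave no such difference, so these cannot be told apart here. The titles name both EA.hy926 and umbilical vein endothelial cells, so cells other than the named line may also be the source, and no biological explanation was tested.

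With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Among protein-coding genes the real split gave 7 calls and the highest other 3, with 1 split, the real one, having as many. Among lncRNA transcripts the real split gave 7 and the highest other 12, with 5 splits having as many or more. Among protein-coding transcripts these numbers were 26, 30 and 4, among all annotated genes 8, 4 and 1, and among lists called by camera 13, 10 and 1. The lowest other split gave 18 calls among protein-coding transcripts and 3 among lncRNA transcripts, against 0 in both gene tables. An adjusted p under 0.05 in the transcript tables thus also arose in every split that mixed control and LPS.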

How the results depend on the processing

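The alternatives restricted to lncRNA transcripts of genes not annotated as protein-coding, alone or summed per gene, were chosen after seeing the data, and the other alternatives were planned. Of the 116 named genes and transcripts, 1565 recomputed values kept their direction and side of the threshold, 108 kept their direction but lost the call, 2 gained one and 62 changed sign. Of 28 tested lists the counts were 383, 41, 11 and 13. Among the named features, only the 7 called protein-coding genes and the 7 called lncRNA transcripts had a call to lose. All 108 losses were therefore theirs, while most of the 116 never had a call, so the 1565 does not measure how well the calls held. The sign changes were all among features and lists without a call, and the cause was not tested. Scaling alternatives moved the median log2 change of all features by less than 0.1, and robust eBayes has no counterpart for camera.

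The 7 calls among protein-coding genes became 0 without a filter (16077 genes tested, 1563 at an unadjusted p under 0.05) and 105 at an unadjusted p under 0.05 with at least 2-fold change, and ran from 0 to 8 when 1 library was left out. The pseudocounts of 0.1 and 1, the minimum of 1 FPKM, both scalings, library weights and robust eBayes gave 6 to 8. The 7 calls among lncRNA transcripts became 1 without a filter (55877 tested), 260 at an unadjusted p under 0.05 with at least 2-fold change, 4 of 866 among transcripts of genes not annotated as protein-coding (3 of them shared) and 3 of 831 when those were summed per gene, and ran from 0 to 7 with 1 library left out. Those sums left out transcripts outside the lncRNA class. Their 3 calls therefore repeat the single-transcript log2 changes of AC027319.1 (−3.92), AP003396.5 (3.99) and AL118506.1 (2.24). Summed over all transcripts, these genes changed by −0.36, 0.43 and 0.87, so the 3 calls are no separate support at gene level. The 26 calls among protein-coding transcripts became 15 without a filter (52008 tested) and 685 at the unadjusted threshold with 2-fold change, and ran from 27 to 49 with 1 library left out. The 8 calls among all annotated genes became 5 with a pseudocount of 1, 5 after quantile normalization, 0 without a filter (33999 tested, 2196 at an unadjusted p under 0.05 by limma) and 149 at the unadjusted threshold with 2-fold change, and ran from 1 to 6 with 1 library left out. Without a filter more features share the adjustment, and with a library left out fewer samples enter the fit. Lower power from fewer samples does not explain why the protein-coding transcript count rose from 26 to between 27 and 49. Other causes of these changes were not tested. Of 28 lists, 13 were called by camera with the preset correlation, 10 to 15 with 1 library left out, 0 with an estimated correlation and 1 by fry.

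Among 6 of the 7 called protein-coding genes, limma's adjusted p ranged over the 6 fits with 1 library left out from 0.0228 to 0.147 for MX1, from 0.0404 to 0.121 for ISG15, from 0.0128 to 0.147 for IL4R, from 0.0426 to 0.121 for BRD2, from 0.0128 to 0.121 for UBTD2 and from 0.098 to 0.168 for CORO1C. CORO1C lost its call in each of these fits. Over the 6 fits the adjusted p of AC027319.1-201 ranged from 0.0277 to 0.116, that of ATP5PB-201 from 0.0178 to 0.128 and that of AL118506.1-201 from 0.12 to 0.207.

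Control and LPS libraries share replicate numbers, and whether the numbers pair them stayed unsettled, so they were treated as unpaired. Same-numbered libraries' deviations from their group means correlated at 0.0175, 0.105 and 0.0605 across protein-coding genes and at 0.026, 0.121 and 0.0926 across all annotated genes, not all above 0.1. Every library correlated best with its own number across all annotated genes, and all but control 1 did so across protein-coding genes. Size factors also ran alike by number in control and LPS libraries, at 1.003 and 0.9918 (replicate 1), 0.9822 and 0.9719 (replicate 2) and 1.039 and 1.045 (replicate 3). These are hints of pairing from the data, not from the design. A fit with the replicate block gave 0 calls among protein-coding genes, 0 among lncRNA transcripts, 0 among protein-coding transcripts and 0 among all annotated genes, with 1451, 420, 1171 and 1736 features at an unadjusted p under 0.05 by limma, and 14 of 28 lists by camera, the 13 of the fit without the block and cholesterol synthesis (adjusted p = 0.0295, in a range from 0.00703 to 0.738 over its alternatives). It changed no other list's call. The block leaves fewer residual degrees of freedom. Even so, limma's counts at an unadjusted p under 0.05 rose with it from 1254 among protein-coding genes, 413 among lncRNA transcripts and 1468 among all annotated genes. Among protein-coding transcripts the count fell from 1324.

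Settings other than leaving out a library turned the log2 change of FTL to 0.00456 and that of RPLP0 to 0.000135 with median-of-ratios rescaling. Quantile normalization turned ACTB to −0.0104, RPLP0 to 0.0565, GAPDH to −0.0242 and CALR to −0.0146, and library weights turned COX6A1 to −0.00122 and CALR to −0.00802. With a minimum of 1 FPKM camera's direction for the LPS receptor list turned, at a median of −0.00507. The cause was not tested.

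Leaving out 1 library at a time moved the log2 change through 0 for ACTB (−0.124 to 0.206), ALDOA (−0.015 to 0.109), CALR (−0.114 to 0.0727), CDH5 (−0.0831 to 0.221), COL1A2 (−0.0711 to 0.0318), COX6A1 (−0.0153 to 0.0319), ENO1 (−0.0822 to 0.274) and F3 (−0.0612 to 0.247). The same held for FDPS (−0.000196 to 0.313), FTL (−0.0323 to 0.0135), GDF15 (−0.298 to 0.0265), HSP90AB1 (−0.0513 to 0.0974), HSPA5 (−0.179 to 0.0735), HSPB1 (−0.0896 to 0.0552), IRAK1 (−0.124 to 0.0274) and LY96 (−0.152 to 0.0474). Among further genes without a call, it ran over MALAT1 (−0.206 to 0.508), MCL1 (−0.183 to 0.0373), MCM6 (−0.058 to 0.128), MSMO1 (−0.0354 to 0.238), MYD88 (−0.0782 to 0.138), PCNA (−0.0395 to 0.121), RMRP (−0.126 to 0.0125) and RPL13A (−0.0341 to 0.0069). The other genes whose sign turned were RPLP0 (−0.139 to 0.178), RPPH1 (−0.0474 to 0.221), RPS2 (−0.0929 to 0.0915), SREBF2 (−0.0243 to 0.0962), THBD (−0.0718 to 0.185), TPX2 (−0.0014 to 0.331), VIM-AS1 (−0.6155 to 0.128) and VWF (−0.0114 to 0.3003). The cause was not tested beyond there being fewer samples.

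Camera's direction turned when 1 library was left out for 9 lists without a call, whose median log2 changes ran over these ranges: LPS receptor and its signalling (−0.0547 to 0.0103), cholesterol synthesis (−0.0243 to 0.242), coagulation and fibrinolysis (−0.13 to 0.0022), fibroblast and smooth muscle markers (−0.0939 to 0.017), housekeeping genes (−0.0818 to 0.132), hypoxia and glycolysis (−0.0837 to 0.0283), immediate early genes (−0.105 to −0.0134), p53 target genes (−0.0832 to 0.0599) and unfolded protein response (−0.109 to −0.00732). The cause was not tested.

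Absolute depth is unknown for these FPKM tables, so no detection limit can be given for features listed at 0. On simulated data with normal noise, 0% of 4-fold changes among 8297 lncRNA transcripts and 11% among 20563 protein-coding transcripts were recovered. A count near 0 in those tables therefore does not speak against changes of that size. The simulation says nothing about false calls from transcripts that switch on or off between libraries.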

Other observations

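These genes and transcripts were chosen only after their values were seen, and no explanation for them was tested.

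Several genes differed strongly between libraries of the same group. IFITM2 stood at 3.05 FPKM in control 1 and at 46.7 and 60.2 FPKM in the other control libraries. MT-CO3, which has nuclear copies and is uncertain, stood at 4.97, 64.0 and 23.6 FPKM in controls and at 3.70, 62.4 and 71.4 FPKM with LPS. HSPA1A, which has a near-identical copy and is uncertain, stood at 0.615 FPKM in control 2 and at 8.997 and 10.2 FPKM in controls 1 and 3.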
